A study of Mus musculus with 2 samples.

How the data were processed

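Total RNA from the livers of 45-day-old male mice was profiled for miRNAs on 2 arrays, 1 for floxed controls and 1 for liver-specific Hnf4a-null mice. Whether an array holds RNA of a single animal or of several is not given in the sources used here. Per the labels' protocols, RNA was purified with a small-RNA-retaining column kit and labelled with the red dye Hy5, and each sample has 1 channel. The authors deposited 1 table of processed array intensity values on a linear scale. The array design, scanner software, background correction, filter on dim spots and normalization are not given in the sources used here. Of the 610 features in the table, 604 carry a single miRBase mature-sequence accession and 6 carry several, for 620 distinct accessions. One accession is listed in 2 features.

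The table's columns were tested for signs of its scaling. The values are all positive, and the total intensity was 28849 on the control array and 28342 on the liver-null array. The medians of the values given were 4.33 and 3.20, so neither the total nor the median of these values was equal. The missing values may have entered an earlier scaling. These figures therefore cannot show whether the arrays had been scaled to each other. No value is given for 311 features on the control array and for 270 on the liver-null array. The meaning of a missing value is not given in the sources used here, and missing values were not replaced.

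The deposited table does not pair accessions with miRNA names. None of the 620 accessions (0) matched the mouse gene table at hand, which was of the GRCm38.p6 assembly. Names were not assigned from the accessions. The 25 miRNA lists and the 8 miRNAs that were to be named in any case, both fixed before the data were examined, therefore could not be applied, and no result is given by miRNA family, cell type, genomic position or function. For the same reason at most 2 accessions are named in each direction.

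Intensities were converted to log2(intensity + 1), and the difference was taken as liver-null minus control for each of the 258 features with a value on both arrays. A fold change on this scale understates the change of dim features. No further normalization was applied to the main values, and the difference between the 2 arrays' medians over the shared features is given beside them. The plan was to report differences relative to this shift when it passed a set size, as it did at 0.15. The main values and the figures depart from this plan. The counts and the named accessions are given both ways. Counts of features differing at least 2-fold (a log2 difference of 1) were made among the 129 shared features whose mean log2 level was at or above the median mean level. These are called the brighter features below. Brightness depends on the probe as well as on the amount of miRNA, so it describes the signal and does not rank the miRNAs by abundance. The accessions to be named were the 12 highest and 12 lowest differences among the brighter features with a single accession, leaving out a value that is the lowest of its array, and of these the 2 most extreme in each direction are named.

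With 1 array per group there is no replicate error, so no test between the groups was made and no p-value, standard error or interval is given. The number of arrays limits the precision. Each difference compares these 2 arrays and holds the difference between the animals sampled, the hybridizations and the genotypes together.

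The alternatives were centring each array on its median or its 75th percentile, quantile normalization, loess centring of the difference on the mean level (span 0.4), a pseudocount of 16, other filters on dim features, and thresholds of 1.5-fold and 4-fold. Plain log2 values with no pseudocount and a common lowest value for both arrays were added after seeing the data. The counting and scaling steps were run on simulated data with known changes. Those changes lay well beyond the 2-fold threshold, with little added noise and no missing values, so this checked the code only. Recovery was required of the unscaled counts alone. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 were used.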

Results

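HNF4a is a nuclear receptor that drives much of the hepatocyte's gene expression. To find miRNAs that depend on it in the liver, the miRNA profile of liver RNA from mice lacking Hnf4a in the liver (Hnf4aΔH) was set against that from floxed controls (Hnf4af/f). All were 45-day-old males, and each genotype was represented by 1 array, so all values below are single measurements without replicate error. The Hnf4a transcript itself was not among the features analysed here, and the loss of the gene could not be checked in these data.

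A value was given for 299 of the 610 miRNA features in the control liver and for 340 in the liver-null liver. Both arrays gave a value for 258 features and neither gave one for 229. The intensities given ran from 1.45 to 7459 in the control and from 1.02 to 8046 in the liver-null sample. A few features carried most of the signal in both livers. The brightest 10 features held 63.2% of the total intensity in the control and 64.2% in the liver-null sample.

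Of the 10 brightest features on the control array, 9 lay within 2-fold on the liver-null array and 1, MIMAT0000224, was lower by a log2 difference of -3.16. Another feature was the brightest on both arrays, with an intensity of 7459 in the control and 8046 in the liver-null liver. Its log2 difference was 0.11, which became -0.04 with median centring. With quantile normalization the difference was 0 by construction, since this feature was the brightest on both arrays. It held 25.9% of the total intensity in the control and 28.4% in the liver-null sample. The 10 brightest features on the liver-null array all lay within 2-fold, with differences between -0.60 and 0.87. Picking by liver-null intensity leaves out features much lower there. MIMAT0000224 ranked 9 on the control array and 44 on the liver-null array. Over all 258 shared features the log2 levels of the 2 arrays correlated with Pearson's r = 0.960. This is a correlation across features, which are not independent replicates.

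A limited set of miRNAs differed by more than 2-fold. Among the 129 brighter features, 105 (81.4%) lay within 2-fold, 13 were at least 2-fold higher in the liver-null liver and 11 were at least 2-fold lower. The median difference over the brighter features was 0.08, turning to -0.07 with median centring and -0.02 with loess centring, and the middle of the distribution ran from -0.30 at the 25th to 0.55 at the 75th percentile. The median log2 level over the 258 shared features was 0.15 higher on the liver-null array, while the median of the differences of the same features was -0.06, so these 2 measures of a general shift had opposite signs. Relative to the shift of 0.15, 7 brighter features were at least 2-fold higher and 13 at least 2-fold lower, so the share of higher features among those differing by 2-fold went from 54.2% to 35.0%. With loess centring on the mean level, 6 were higher and 13 lower, a share of 31.6%. With a pseudocount of 16, which brings every difference nearer to 0 and most of all those of dim features, 2 were higher and 7 lower. This is a share of 22.2%. The share stayed at 54.2% with centring on the 75th percentile and was 47.8% with quantile normalization. It was 56% with no pseudocount, 54.8% with no filter on dim features and 62% at 1.5-fold. In the brightest quartile alone it was 27.3%, and at 4-fold 25%. Which direction held more features thus depended on the processing.

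MIMAT0000224 had the lowest liver-null value relative to control of any brighter feature. Its intensity was 699 in the control liver and 77.4 in the liver-null liver. This is a 9.03-fold lower intensity, with a log2 difference of -3.16, or -3.31 relative to the median shift. MIMAT0004211 had an intensity of 138 in the control and 21.8 in the liver-null liver, a ratio of 6.30. Its log2 difference was -2.60, or -2.75 relative to the median shift. The 12 lowest differences ran from -3.16 to -0.95, and the median intensity of these features was 82.5 in the control and 22.1 in the liver-null liver.

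**Figure D1:**
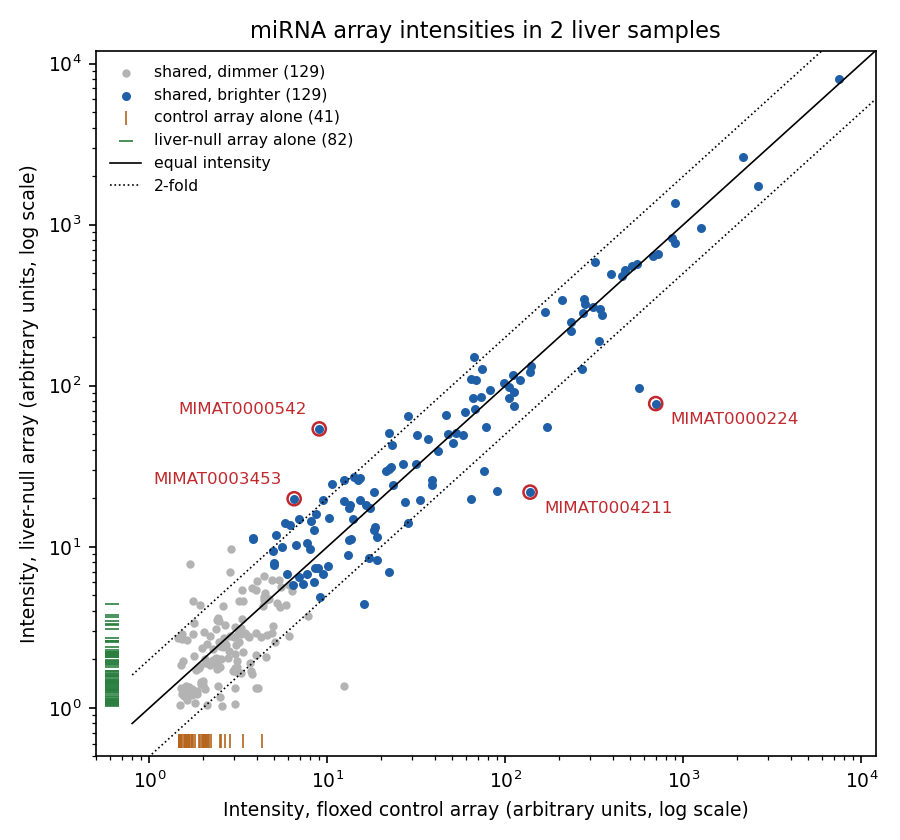
Intensity of each miRNA feature in the floxed control liver (x axis) against the liver-null liver (y axis), both in arbitrary units on log scales, 1 array per genotype. Blue and grey points are the 129 brighter and 129 dimmer shared features. Ticks at the margins are the 41 and 82 features with a value on 1 array alone. The solid line marks equal intensity and the dotted lines a 2-fold ratio of the intensities. Counts in the text use log2(intensity + 1), so dim points outside the dotted lines can fall short of 2-fold there. MIMAT0000224 lies farthest below the line of equal intensity among the blue points, at 699 and 77.4.

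MIMAT0000542 had the highest difference of the brighter features, with an intensity of 8.99 in the control and 53.9 in the liver-null liver. The ratio was 5.99 and the log2 difference 2.46, or 2.31 relative to the median shift and 1.48 with a pseudocount of 16. MIMAT0003453 followed, with intensities of 6.50 and 19.9, a ratio of 3.06 and a log2 difference of 1.48. Relative to the median shift its difference was 1.32. With a pseudocount of 16 it came to 0.67, below 2-fold. The 12 highest differences ran from 1.01 to 2.46. Their median intensity was 7.75 in the control and 22.2 in the liver-null liver. With quantile normalization the 12 highest had a control median of 25.2 and the 12 lowest one of 69.8. Since both sets of 12 were picked by the difference, their control levels differ in part by selection, and their liver-null medians, 22.2 and 22.1, were close.

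Among the signals brightest by their mean over both arrays, more features were at least 2-fold lower than 2-fold higher, except with quantile normalization. This comparison by quartile was made for the main values and the 4 alternative scalings. It was not made with other pseudocounts or at 1.5-fold. Among all 129 brighter features at 1.5-fold, 31 were higher and 19 lower. The majority of lower features in the brightest quartile is therefore not shown to hold below 2-fold. In the brightest quartile of the shared features (65), 8 were at least 2-fold lower in the liver-null liver and 3 at least 2-fold higher. Of these, 3 were at least 4-fold lower and none (0) was at least 4-fold higher. With quantile normalization this quartile held 7 lower and 7 higher features at 2-fold, with 3 still at least 4-fold lower and 0 at least 4-fold higher. In the next quartile down (64 features), 3 were at least 2-fold lower and 10 at least 2-fold higher. This majority turned with median centring, quantile normalization and loess centring, each of which gave 5 lower and 4 higher features there. Outside the brightest quartile, 1 feature was at least 4-fold lower, in the second dimmest quartile. Another 1 was at least 4-fold higher, in the second brightest. The median difference was 0.04 in the brightest quartile, 0.30 in the next and -0.23 in the dimmest.

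**Figure D2:**
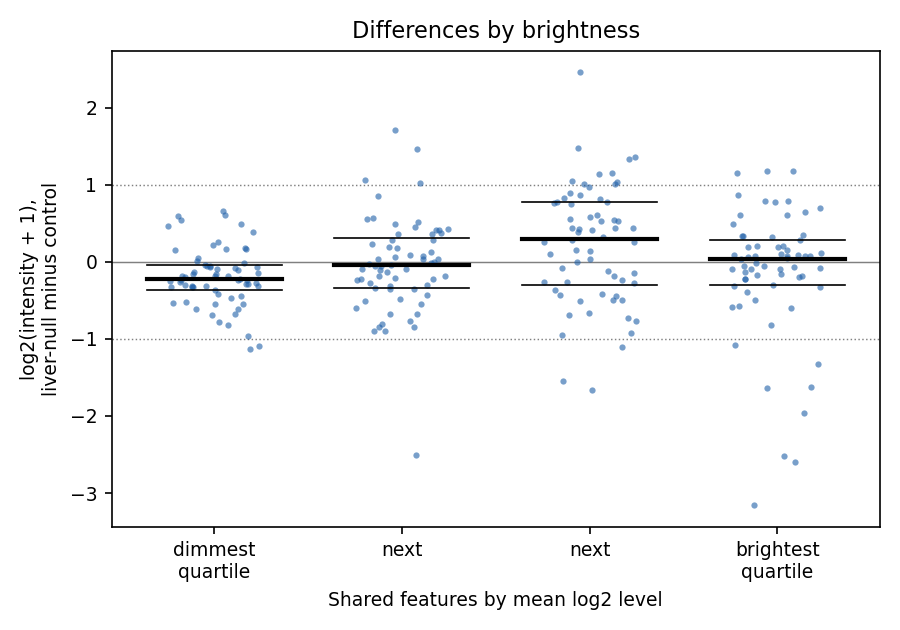
Difference in log2(intensity + 1), liver-null minus control, for each of the 258 shared features (points), in quartiles of the mean log2 level. Thick lines are medians, thin lines the 25th and 75th percentiles, and dotted lines a 2-fold difference; the 3 points below -2 in the brightest quartile are the features at least 4-fold lower, and the median of the dimmest quartile lies at -0.23.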

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

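The test in this part was chosen after the number of features on each array had been seen. A total of 82 features had a value on the liver-null array and none on the control array, against 41 with a value on the control array alone. These features take no part in the comparison of levels, and the 82 were singled out as signal without a counterpart in the control. All were dim. Their liver-null intensities ran from 1.03 to 4.41 with a median of 1.52, and those on the control array alone ran from 1.46 to 4.26 with a median of 1.76. None of either set (0) reached its own array's median over the shared features, which was 6.23 on the liver-null and 5.50 on the control array. A candidate technical explanation is that the liver-null array reported values down to a lower level, 1.02 against 1.45. With 1.45 as a common lowest value on both arrays, 47 features lay above it on the liver-null array alone and 67 on the control array alone, a ratio of 0.70. The excess on the liver-null array was then no longer present, as this explanation requires. Because 1.45 is the control array's own lowest value, the liver-null number could only fall and the control number only rise. The direction of the change was thus fixed in advance. The larger number passed to the control array, so the test does not establish the explanation. Whether any of the 82 miRNAs was present only in the liver-null liver remains untested, since the meaning of a missing value is not given in the sources used here.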

How the results depend on the processing

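No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. Among the brighter features, the main counts were 13 higher and 11 lower at 2-fold. The higher count was the less stable. It was 7 with median centring, 6 with loess centring, 2 with a pseudocount of 16 and 3 in the brightest quartile alone. The brightest quartile is a part of the brighter features, and median centring takes 0.15 from every difference. Neither could therefore raise the higher count. A pseudocount of 16 brings every difference nearer to 0, most of all for dim features. The 12 highest differences had a lower control median, 7.75, than the 12 lowest, 82.5. The fall of the higher count with this pseudocount thus follows in part from the setting. The lower count moved by more than 1.5 times with the pseudocount of 16, to 7, and with the thresholds. At 1.5-fold, 31 features were higher and 19 lower, and at 4-fold 1 was higher and 3 lower. The other 11 of 20 recomputed counts stayed within 1.5 times the main count. Quantile normalization gave 11 higher and 12 lower, of which 7 and 10 were features of the main counts. The 4 named accessions kept their direction under all 6 settings in which they were recomputed, and 23 of these 24 values stayed at or beyond 2-fold. They were picked as the most extreme differences in these same data, and a pseudocount cannot change the sign of a difference. These settings could therefore hardly have reversed them, and the kept direction is no evidence of repeatability. MIMAT0000224 ranged from -3.31 to -2.94, MIMAT0004211 from -2.75 to -2.02, MIMAT0000542 from 1.48 to 2.58 and MIMAT0003453 from 0.67 to 1.61. With a common lowest value, added after seeing the data, the features on 1 array alone went from 41 to 67 for the control and from 82 to 47 for the liver-null array. The averaging of features of 1 miRNA and the settings for miRNA lists were not run, since names were not assigned. The number of arrays limits the precision.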

Other observations

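The test in this part was chosen after the differences had been seen. In the brightest quartile of the shared features, 3 stood at least 4-fold lower in the liver-null liver, and none (0) at least 4-fold higher, while the 25th and 75th percentiles of that quartile were -0.30 and 0.28. The third of them, MIMAT0000224 and MIMAT0004211 being the other two, is not named because accessions are printed for 2 features per direction. The 4 alternative scalings did not remove these differences. Under them the difference nearest to 0 among the 3 was -2.48, and the number at least 4-fold lower was 3 or 4. With no pseudocount this number was 4, and with a pseudocount of 16 it was 3. The 3 were picked for being at least 4-fold lower, and the arrays' medians differed by only 0.15. Scalings of these kinds could hardly have brought them within 2-fold, so the test says nothing about other effects of processing. The hypothesis left open is that these miRNAs depend on Hnf4a in the liver. With 1 array per genotype it cannot be told apart from a difference between the animals sampled or between the hybridizations.

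The median difference between the arrays was -0.23 in the dimmest quartile, -0.05 in the next, 0.30 in the one above it and 0.04 in the brightest quartile. These values depended on the processing. With loess centring, which removes a trend with brightness by construction, they were 0.01, 0.00, 0.09 and -0.07 in the same order. With quantile normalization they were 0, -0.01, 0.11 and 0.09, and with median centring -0.38, -0.20, 0.15 and -0.11. With centring on the 75th percentile they were -0.20, -0.02, 0.32 and 0.06. With the quartiles formed anew for each pseudocount, the dimmest stood at -0.37 with no pseudocount and at -0.03 with a pseudocount of 16. For the features of the main dimmest quartile, the median with no pseudocount was -0.34.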
